A study of Mus musculus with 8 samples.

How the data were processed

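Small RNA was sequenced from mouse testes. Per the labels, total RNA was size selected to 19 to 33 nt, linkers were ligated to the 3' and the 5' end with T4 RNA ligase, and the product was amplified by PCR. The labels describe 8 libraries in 8 groups of 1. These were heterozygous and homozygous Tdrd6 mutants at 18 days, 25 days and 6 weeks after birth, and heterozygous and homozygous Tdrd1 mutants at 18.5 days after conception.

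The values analysed came from 1 table for the whole series, which the authors deposited with 3 columns. Per the file headers, each line held a distinct sequence, the number of positions to which it mapped and a final annotation, which was blank for unannotated sequences. The aligner, the genome build, the annotation sources and their order of precedence, the libraries that were pooled and any minimum read number were not given in the sources used here. No column was tied to a single library (0 of 3), and none held a read number, a coordinate or a strand. The sequencing depth of each library was therefore unknown.

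The design fixed before the data were examined compared homozygous with heterozygous libraries and the ages with each other, using read counts per library. None of these comparisons could be made from a pooled table, because no sequence could be assigned to a library. The pooled list was described in their place. Every value is a number or share of distinct sequences, each counted once however often it was read, so no value measures the abundance of an RNA. Where a share is given, its 95% interval is exact (Clopper-Pearson) and covers counting error only. Distinct sequences of overlapping fragments are not independent molecules, and no test was run and no p-value computed.

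Annotations were sorted into classes by their names: RefSeq mRNA accessions, repeat names, miRNA hairpins, ribosomal RNA, transfer RNA, other structural RNA, other annotations and blank. Of 17267 RefSeq accessions, 16820 had a gene symbol in the RefSeq table used here. Sequences of 24 to 33 nt were called piRNA-length, and 25 to 32 nt was the alternative fixed before the data were examined. Repeat and miRNA lists were also fixed then. The rule for names was that members of a list with at least 500 sequences are named, 2 to 4 per list with the most abundant first, and that the 10 mRNA genes with most piRNA-length sequences are named. The 10 noncoding and 10 coding genes with most transcript matches were added after the data had been seen (1 of the coding genes is not reported here), as were the genes and hairpins said to have been picked afterwards.

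Partners on the opposite strand were sought without coordinates. A 5' end was defined by the first 20 nt of a sequence. For each overlap from 10 to 20 nt, the reverse complement of the last 10 bases of the overlap was compared with the first 10 bases of all 5' ends of the same list, so that 10 bases were compared at every overlap. The 10 overlaps from 11 to 20 nt served as background. The same comparison against as many random mRNA 5' ends, with only those 5' ends that had A at the pairing position, and against the other of the young L1 and IAP lists, measured what base composition alone gave. For mRNA and unannotated sequences, 60000 random 5' ends were used.

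Sequences of piRNA length that mapped to 1 position, 3954461 in all, were matched exactly and over their whole length to both strands of 141767 GENCODE release M21 transcripts of the mouse genome GRCm38. The transcripts are spliced, so introns were not searched. Sequences annotated to miRNA hairpins were matched whatever their map number. Sequences that matched transcripts of exactly 1 gene, 1013721 in all, were counted for that gene. They are unique by the authors' map number, whose genome build was not given. Coordinates are those of the GENCODE gene on GRCm38. For the 5' untranslated region, coding sequence and 3' untranslated region, the transcript with the longest coding sequence among those with both untranslated regions represented each gene with at least 50 sense matches, and the first base of a sequence decided its region. Phasing was measured on the longest transcript of each gene, as the share of sense 3' ends followed by a sense 5' end at distances from 1 to 20 nt.

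The functions were tested on simulated data. All 4000 simulated sequences with a known transcript position and strand were found there, and 0 of 1000 random sequences were matched. Of 8400 simulated 5' ends, 57.1% were made with a partner and 57.6% were found with one at 10 nt, against at most 1.01% at other overlaps. All 800 simulated 3' ends that were followed by a 5' end were found among 4800. The simulated sequences were random, without base preferences or repeats, and those for phasing had no other sequences nearby. In the data the background was far higher, with a mean of 40.9% at other overlaps in young L1 and 29.3% at other distances on noncoding genes. The simulations therefore tested the counting, not how specific it was in the data.

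The alternatives were the 25 to 32 nt window, sequences that map to 1 position, each 5' end counted once, shares without structural RNA, other partner sets, and other choices of transcript and gene minimum. Their effect is given with the closing observations. Sequences of 15 to 18 nt and 34 to 36 nt were left out of the measurements of bases, partners and transcript matches. The annotation shares, the share that mapped to 1 position and the numbers of annotations and hairpin sequences cover all lengths. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.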

Results

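Small RNAs of mouse testes were sequenced to compare mutants of Tdrd1 and Tdrd6, which encode Tudor-domain proteins that bind the Piwi proteins of male germ cells. The labels gave heterozygous and homozygous Tdrd1 testes at 18.5 days after conception and heterozygous and homozygous Tdrd6 testes at 18 days, 25 days and 6 weeks after birth, with 1 library in each of the 8 groups. The values analysed were a single list of 6246223 distinct sequences in which no sequence was tied to a library. The Tdrd1 comparison, the Tdrd6 comparison at each of the 3 ages and the comparison between ages were therefore not made, and the levels of the targeted genes could not be used to check the labels. The account below describes which RNAs were present in the pooled list. Counts refer to distinct sequences, not to reads, and the depth of the libraries was unknown. There were no replicates. Intervals cover counting error only.

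The pooled list was made up mainly of piRNA-length sequences, the size of the small RNAs bound by Piwi proteins. The most frequent length was 27 nt, and 4883266 sequences (78.2%) were 24 to 33 nt long. Another 871566 sequences (14.0%) were 19 to 23 nt long. This is the size range of miRNAs, but only 1.05% of them were annotated to miRNA hairpins and 55.2% were unannotated. Of all sequences, 77.5% mapped to 1 position. Sequences without annotation formed 50.5% of the list, those annotated to repeats 32.8% and those annotated to RefSeq mRNAs 15.2%. Ribosomal RNA gave 0.627%, transfer RNA 0.287%, miRNA hairpins 0.281% and other structural RNA 0.267%. The annotations comprised 786 repeat names, 17267 mRNA accessions and 385 miRNA hairpins.

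**Figure D1:**
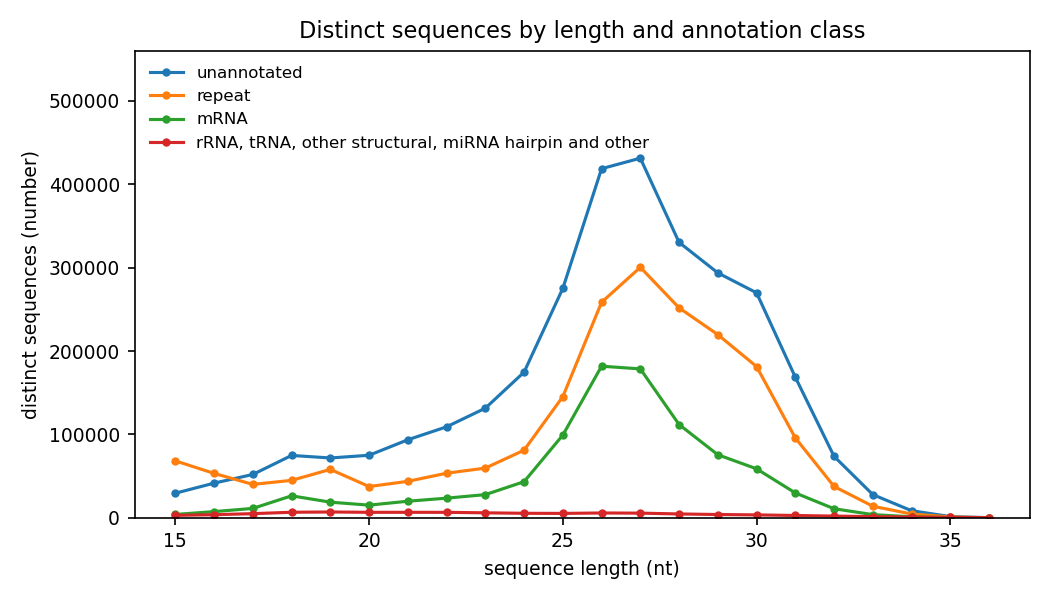
Number of distinct sequences at each length in nt, with 1 line per annotation class. The lines of unannotated and repeat sequences peak at 27 nt, and that of mRNA sequences peaks at 26 nt.

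Unannotated, repeat and mRNA sequences of piRNA length shared a strong preference for T, which stands for U in the RNA, as first base. The share with T first was 78.4% (95% interval 78.3 to 78.5) in mRNA sequences, 71.2% (71.1 to 71.3) in repeat sequences and 69.4% (69.3 to 69.4) in unannotated sequences. Structural RNAs of the same length had it less often, with 31.1% (30.4 to 31.7) in ribosomal RNA, 31.6% (30.6 to 32.6) in transfer RNA and 47.2% (46.1 to 48.2) in other structural RNA. Sequences of 19 to 23 nt had T first in 45.1% of cases. At position 2 the share of T was 16.8% in mRNA sequences and 21.3% in repeat sequences. The modal length was 27 nt for unannotated and repeat sequences and 26 nt for mRNA sequences. There were 1.90 distinct sequences per 5' end among unannotated sequences, 1.61 among repeat sequences and 1.20 among mRNA sequences. Per 3' end there were 1.62 among unannotated and 1.08 among mRNA sequences.

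Retrotransposons of every listed kind were represented, from autonomous L1 elements and endogenous retroviruses to short SINEs. The 10 lists held all but 33.0% of the 1585321 repeat sequences of piRNA length. Of these, young L1 elements gave 7.69%, older L1 elements 13.1%, IAP elements 8.14%, MaLR elements 11.5% and B1, B2 and B4 SINEs 8.23%, 6.68% and 5.22%. MMERVK10C, ETn/MusD and MERVL elements gave 3.47%, 1.75% and 1.27%. Lists were assigned by name, so their limits are approximate. RLTRETN_Mm with 4921 sequences was counted among the other repeats, and MT2A with 5946 and MT2C_Mm with 5883 under MaLR. The most frequent names within the lists included IAPEz-int with 55866 sequences, the young L1 subfamilies L1Md_F2 with 44671, L1Md_T with 31520 and L1Md_A with 23646, the SINEs B3 with 37264, B2_Mm2 with 30546, ID_B1 with 29011, B1_Mus1 with 24521, RSINE1 with 21274 and B1_Mus2 with 17680, and MMERVK10C-int with 20946 and RLTR10-int with 12717. MERVL-int had 16279 sequences, MT2_Mm, its long terminal repeat, 3824, IAPEY3-int 15940, MTD and MTC of the MaLR group 15925 and 13751, L1_Mus1 and Lx8 of the older L1 elements 13949 and 12687, and MMETn-int and ETnERV2-int 11153 and 10906.

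The lists of young L1 and of endogenous retroviruses differed from mRNA sequences in a second base preference. A at position 10 was found in 44.6% (44.3 to 44.9) of young L1 sequences, 42.8% (42.1 to 43.5) of MERVL, 42.6% (42.0 to 43.2) of ETn/MusD, 42.4% (42.1 to 42.6) of IAP and 41.1% (40.7 to 41.5) of MMERVK10C sequences. B1 and B2 SINEs had 40.1% and 38.1%, MaLR elements 36.1%, older L1 elements 32.7% and B4 SINEs 30.6%. The share was 25.8% (25.7 to 25.9) in mRNA, 28.5% in unannotated and 25.4% in ribosomal RNA sequences. In young L1 it exceeded the mean of positions 9 and 11 by 19.4 percentage points. Sequences that did not start with T had A at position 10 more often than those that did. The shares were 63.4% and 32.2% in MERVL, 61.5% and 35.6% in ETn/MusD, 54.5% and 35.8% in IAP and 53.8% and 39.4% in young L1. B1 SINEs showed no such contrast, with 40.1% in both.

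**Figure D2:**
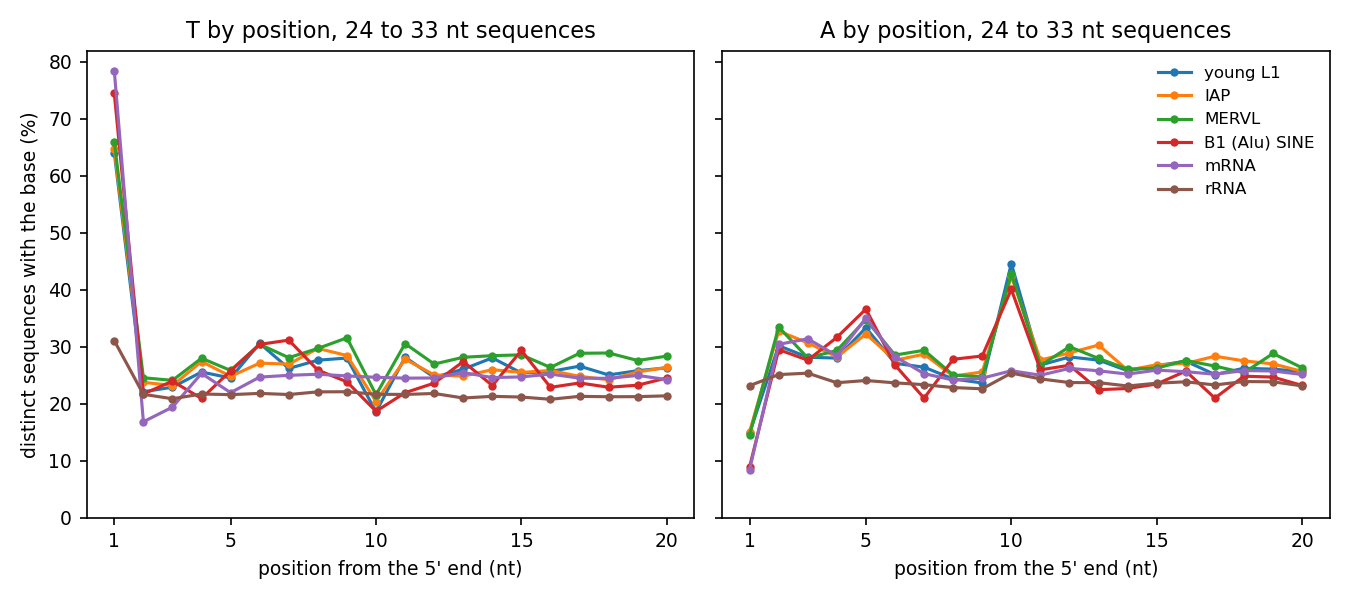
Share of distinct 24 to 33 nt sequences with T (left) or A (right) at each of the first 20 positions from the 5' end, in percent, with 1 line for each of 4 repeat lists, mRNA and ribosomal RNA. T is highest at position 1 in every line, from 31.1% in ribosomal RNA to 78.4% in mRNA, and A is highest at position 10 in the 4 repeat lists drawn, with 44.6% in young L1 against 25.8% in mRNA and 25.4% in ribosomal RNA.

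The pairs of bases went with a difference in length in many lists. In MMERVK10C, sequences with A at position 10 and another first base than T were on average 0.528 nt longer than those with T first and another base at position 10. The modal lengths were 28 nt and 27 nt. In ETn/MusD the difference in mean length was 0.52 nt, in MERVL 0.409 nt and in young L1 0.285 nt. It was not limited to lists with frequent A at position 10, since B4 SINEs had 0.434 nt and mRNA 0.186 nt, while unannotated sequences had -0.057 nt. In young L1 the share of A at position 10 was lowest at 25 nt (37.5%) and highest at 29 nt (49.8%), with 39.8% at 24 nt and 45.3% at 33 nt.

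Opposite-strand sequences whose 5' ends overlapped by 10 nt, the arrangement left by reciprocal (ping-pong) cleavage of sense and antisense transcripts, were in excess in the retrotransposon lists. Of 66860 young L1 5' ends, 55.3% (54.9 to 55.6) had such a partner, against a mean of 40.9% (SD 1.86) over the 10 overlaps from 11 to 20 nt and a highest value of 43.8%. The shares were 50.1% against 36.4% in IAP, 49.5% against 32.3% in MERVL, 43.1% against 27.02% in MMERVK10C, 42.5% against 32.5% in B1 SINEs and 31.5% against 16.3% in ETn/MusD. In random mRNA 5' ends they were 8.13% and 7.61%, and in random unannotated 5' ends 10.6% and 9.26%. Young L1 5' ends also found more partners at 10 nt among random mRNA 5' ends, 12.2% against 8.29%. The ratio of the value at 10 nt to the mean of the other overlaps was lower within the list than with mRNA partners for young L1 (1.35 and 1.475), IAP (1.38 and 1.397) and B1 SINEs (1.31 and 1.365), and higher within the list for the other 7 lists, among them ETn/MusD (1.93 and 1.505), MMERVK10C (1.595 and 1.41) and MERVL (1.535 and 1.48). For sequences that mapped to 1 position it was higher within the list in all 10, with 2.43 and 1.53 in young L1 and 2.02 and 1.497 in IAP. With A required at the pairing position, the value at 10 nt was 1.23 times the mean of the other overlaps within young L1, 1.14 times with mRNA partners and 1.17 times with partners from the IAP list, and the corresponding ratios for IAP, with young L1 as the unrelated list, were 1.19, 1.12 and 1.13. The ratios lay further apart for sequences that also mapped to 1 position. Of these young L1 5' ends, 44.9% had a partner at 10 nt in their own list, against a mean of 23.1% at the other overlaps, while random mRNA 5' ends gave 8.42% and 7.43% and 5' ends of the unrelated IAP list, in which A at position 10 was about as frequent, gave 7.92% and 5.48%. The ratios were 1.94, 1.13 and 1.45, and for IAP 1.56, 1.20 and 1.21.

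**Figure D3:**
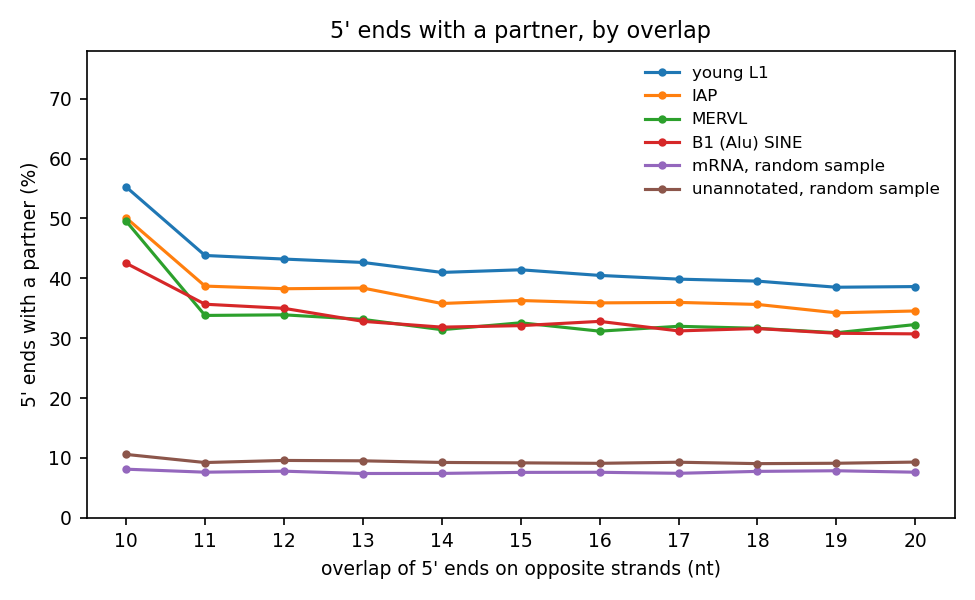
Share of 5' ends, in percent, with a partner on the opposite strand at each overlap from 10 to 20 nt, with 1 line per repeat list and 1 each for 60000 random mRNA and unannotated 5' ends. The value at 10 nt stands above all other overlaps in the 4 repeat lists drawn, for example 55.3% in young L1.

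On annotated transcripts, a few long noncoding RNAs held a large part of the noncoding matches, as is known for the precursors of meiotic (pachytene) piRNAs. Of 3954461 sequences that mapped to 1 position, 26.7% matched a transcript exactly, and 85.5% of these matched the sense strand only. Noncoding genes had 234879 sense sequences, of which 47.1% came from the 10 genes with most. Gm21269 (chromosome 7, 73816546 to 73838898, plus strand) had 23729 sense and 1051 antisense sequences, and Gm10619, its neighbour on the minus strand (73781429 to 73816503), had 9579 and 230. Gm49794 (chromosome 17, 27354111 to 27367492) had 21032 sense sequences, and Gm10505 upstream on the same strand (27325035 to 27344833) had 9742. 1700001L05Rik (chromosome 15, 83353847 to 83367282) had 10237 sense sequences and 2 antisense, and Gm30132 (chromosome 8, 93415537 to 93427628) had 9624 and 4. The others were AC140207.2 on chromosome 18 with 8223 sense sequences, Gm21388 on chromosome 3 with 6538, 4930444F02Rik on chromosome 10 with 5998 and 1700029M20Rik on chromosome 4 with 5967. These 10 genes were picked after the data had been seen.

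**Figure D4:**
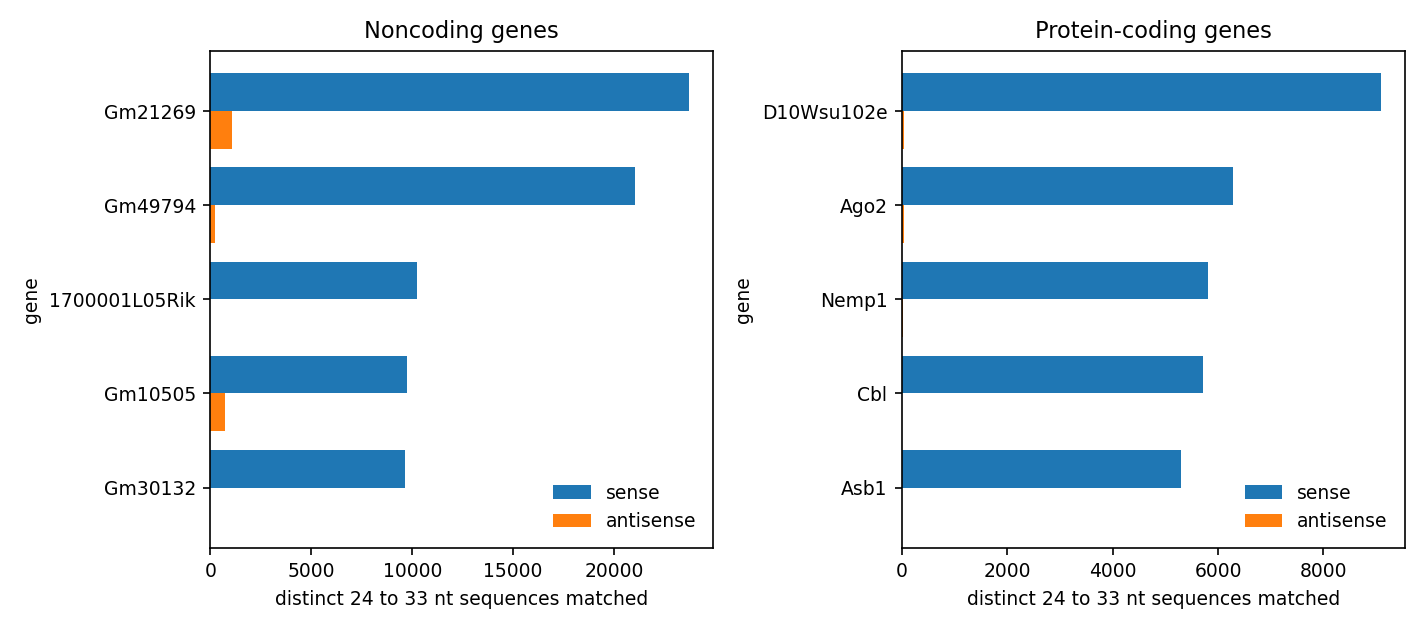
Distinct 24 to 33 nt sequences matched to the sense and the antisense strand of the 5 noncoding (left) and the 5 protein-coding (right) genes with most sense matches, on separate scales. The bars run from 9624 to 23729 sense sequences on the left and from 5298 to 9091 on the right, and the antisense bars are far shorter or not visible.

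Protein-coding genes held more sense sequences in total, 656915, but spread over many more genes. The first 10 had 7.92% of them, and 847 genes were needed for 50% of the sequences, against 12 noncoding genes. D10Wsu102e (chromosome 10, 83360221 to 83488505) had 9091 sense sequences, although its annotated transcript is 123179 nt long and the density was 73.8 per kb. Ago2, which encodes an Argonaute protein of the miRNA pathway (chromosome 15, 73095844 to 73184935), had 6284. Nemp1, of the inner nuclear membrane, had 5810, Cbl, which encodes a ubiquitin ligase, 5721, Asb1 5298, 1700006A11Rik 4135, Tbl2 3958, Eif4ebp2, which encodes a translation repressor, 3518 and the RNA helicase gene Ddx19b 3348. None of these named genes, also picked after the data had been seen, had more than 32 antisense sequences. T was first in 77.8% (77.7 to 77.9) of coding and 66.1% (65.9 to 66.3) of noncoding sense sequences. Sequences of 29 to 31 nt formed 31.8% of noncoding and 23.8% of coding sense sequences.

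Coding genes with many sequences had them in the 3' untranslated region more often than its length predicted, and genes with fewer did not. In the 408 genes with at least 200 sense sequences, 78.5% (78.3 to 78.6) of the sequences started in the 3' untranslated region, which had 65.6% of the transcript length. In the 1981 genes with at least 50 and under 200, the share was 48.0% (47.8 to 48.2) against 48.5% of the length, and 939 genes had a share above that of the length. The split at 200 was made after the data had been seen. Over all 2389 genes with at least 50 sense sequences, 64.97% (64.8 to 65.1) of the sequences started in the 3' untranslated region, which had 52.4% of the transcript length, 30.98% in the coding sequence with 42.3% of the length and 4.05% in the 5' untranslated region with 5.31%. The densities were 44.2, 26.1 and 27.2 sequences per kb. In Ago2 the 3' untranslated region held 98.6% of the sequences and 80.2% of the length, in Cbl 99.1% and 74.5%, and in Ddx19b 81.9% and 51.3%. The shares were nearly equal in Nemp1, with 79.2% and 77.6%, and in 1700006A11Rik, with 20.5% and 18.6%, and in D10Wsu102e the share of sequences, 98.98%, was below that of the length, 99.5%. Of the 2389 genes, 1246 had a 3' share above its share of the length. T was first in 81.1% (81.0 to 81.3) of sequences from the 3' untranslated region, 76.3% (76.0 to 76.5) from the coding sequence and 70.1% (69.4 to 70.8) from the 5' untranslated region.

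By the deposited mRNA annotation, Kcnk10, which encodes a potassium channel, led with 14102 piRNA-length sequences, followed among the genes with a symbol by Asb1 with 5073, the protein kinase C gene Prkca with 4373, the Polycomb gene Cbx7 with 3352, Tbl2 with 2579, Ddx19b with 2572, the tyrosine kinase gene Abl2 with 2019, Arhgap20 with 2001 and the heterochromatin protein gene Cbx5 with 1963. The other accession among the first 10 had no symbol and ranked between Kcnk10 and Asb1, with 6407 sequences. Of its sequences that mapped to 1 position, 99.7% matched a transcript, with Gm5878 and Gm43959 among the genes matched. These 10 held 5.60% of the 793803 mRNA sequences of piRNA length. For 6 of the genes, Asb1, Tbl2, Ddx19b, Abl2, Arhgap20 and Cbx5, at least 98.5% of the sequences that mapped to 1 position matched sense exons of the named gene. The share was 0.163% for Kcnk10, 0.344% for Prkca and 2.71% for Cbx7, so these 3 names did not stand for sequences of the spliced mRNA in the annotation used here. The mismatch was not limited to them. Of all 780967 mRNA sequences of piRNA length that mapped to 1 position, 68.97% matched any transcript. Of those matched, 8.72% matched the antisense strand only.

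The miRNA lists of embryonic, germline and somatic cells were almost all represented in the pooled list. There were 17558 sequences annotated to hairpins, of which 52.3% were 19 to 23 nt and 19.3% were 24 to 33 nt long. The median was 41 distinct sequences per hairpin name. All lengths from 15 to 36 nt are counted here, also those outside the labelled size range. No listed hairpin reached the minimum of 500 sequences for a name, so the examples given here were picked afterwards. All 9 hairpins of the let-7 family had sequences (703 in all, 123 from let-7a), as did all 5 of the miR-34b/c and miR-449 group, which is abundant in meiotic and postmeiotic germ cells (271, with 92 from mir-34c). The X-linked testis cluster had 17 of 18 members (973 sequences), the imprinted Dlk1-Dio3 cluster 46 of 47 (2145), the miR-17-92 group 13 of 13 (822) and the miR-290-295 cluster of pluripotent and primordial germ cells 7 of 7 (248). The miR-200 family had 5 of 5 members with 129 sequences. Hairpins of other tissues were present too. The list for testis somatic cells and stroma had 10 of 10 members (871 sequences), that for blood 5 of 5 (262), mir-126 of endothelium 77 sequences, that for muscle 4 of 4 (70) and that for neural tissue and liver 3 of 3 (76). As these are numbers of sequence variants, they do not rank the miRNAs by level.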

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

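Sequences outside the size range that the labels give drew attention because the measurements of bases, partners and transcript matches did not use them. Their base content was chosen for description only after they had been seen.

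There were 472210 distinct sequences of 15 to 18 nt, 7.56% of the list, below the labelled minimum of 19 nt. T was first in 28.1% (27.9 to 28.2) of them, against 71.2% of sequences of 24 to 33 nt, and 40.7% mapped to 1 position. Of the 152855 sequences of 18 nt, 32.6% (32.3 to 32.8) were identical to the start of a sequence of 24 to 33 nt. Among those, 41.8% began with T, against 23.7% of the remainder.

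Above the labelled maximum of 33 nt there were 19181 distinct sequences of 34 to 36 nt, 0.307% of the list. T was first in 68.1% (67.5 to 68.8), which was close to the share in the main size range, and 5.40% were annotated to ribosomal RNA.

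Samples far from the others and differences between groups were not sought, because no value belonged to a single library.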

How the results depend on the processing

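All alternatives except the 25 to 32 nt window for base shares, the annotation shares at 24 to 33 nt and those without structural RNA were chosen after the data had been seen. No paired analysis was possible because no column belonged to a single library, and the alternatives set beforehand for read counts per library (other scalings, read minimums, count models, blocks by age or genotype, left-out ages) were not run for the same reason. In all, 45 of 54 alternatives left the counting interval of the main value. Only the excess of partners has a sign, and 0 of its alternatives reversed. Those with random mRNA partners or partners of the unrelated list were controls for base composition. Their positive excess therefore does not speak for the stability of the result, although they are counted among the 54 and the 45. The other values are shares, which have no sign and could not reverse. Set against the transcript length, the share of the 3' untranslated region did turn. It was 64.97% against 52.4% of the length in the main setting, but 48.0% against 48.5% in genes with under 200 sequences. Depth per library, which was unknown, limits every value. The causes were not tested.

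T at position 1 was 70.2% (unannotated), 79.2% (mRNA) and 71.7% (repeat) at 25 to 32 nt, 66.2%, 76.3% and 69.2% with each 5' end counted once, and 74.4% in repeat sequences that map to 1 position. A at position 10 was 40.8% in young L1 and 39.4% in IAP for sequences that map to 1 position, 40.2% and 39.0% with each 5' end counted once, and 26.0% in mRNA at 25 to 32 nt. The unannotated, repeat and mRNA shares were 57.0%, 22.9% and 19.2% for sequences that map to 1 position, 51.1%, 33.2% and 15.4% without structural RNA, and 43.8%, 33.0% and 22.6% with each 5' end counted once. At 24 to 33 nt the repeat share was 32.5% and the mRNA share 16.3%.

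The excess of partners at 10 nt over the mean of other overlaps, 14.3 points in young L1 and 13.7 in IAP, was 15.7 and 11.5 points for sequences that map to 1 position, 3.94 and 2.95 with random mRNA partners, and 1.41 and 1.32 with both. With A at the pairing position it was 13.1 and 10.8 (3.09 and 2.40 with random mRNA partners, 2.23 and 1.46 with partners of the unrelated list), and 21.7 and 12.5 for such sequences that map to 1 position (0.998 and 1.43, and 2.44 and 1.18, with the same other partners). The share of the 3' untranslated region was 67.5% (of the length, 54.6%) on the transcript with most matches, 78.5% (65.6%) in genes with at least 200 sequences, 48.0% (48.5%) in those with fewer and 63.5% with each 5' end counted once. Ranked by 5' ends, 9 of the 10 noncoding and 9 of the 10 coding genes remained.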

Other observations

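Of the tests of explanations in this part, those on the composition of retrotransposons, on structural RNA and on single hairpins were chosen only after the result was seen, as were the partner comparisons that required A at the pairing position and all genes named here.

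Some annotated genes were matched mainly on the strand opposite to the gene. CT025671.4 (chromosome 17, 66193352 to 66199820) had 5627 antisense and 235 sense sequences, with T first in 56.9% and 28.5%. Gm42811 on chromosome 6 had 5501 and 127, Stox1 on chromosome 10 had 3723 and 211, Gm18609 on chromosome 6 had 3657 and 1 and Gm44168 had 2583 and 24. 5330409N07Rik (chromosome 12, 98444817 to 98448334) had 5037 antisense and 8 sense sequences. It lies within Kcnk10 (98429437 to 98578310, minus strand). Of the Kcnk10 sequences that mapped to 1 position, 8.02% matched transcripts of Kcnk10, 1108 of them antisense and 23 sense. Any transcript was matched by 41.04%, chiefly 5330409N07Rik.

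Not all names of endogenous retroviruses shared the preference for A at position 10. MurERV4_19-int, with 9140 sequences, had it in 27.9%, close to unannotated sequences, and RLTR14-int, with 6942, in 26.1%. Their sequences mapped mostly to 1 position, with 93.5% and 98.5%, against 13.6% in IAPEz-int and 22.8% in MERVL-int. The MaLR element MTA_Mm had A at position 10 in 52.4% of 8072 sequences.

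Retrotransposon sequences had A at position 10 more often than mRNA sequences. A-rich composition would raise the neighbouring positions as well, but in young L1 position 10 lay 19.4 percentage points above the mean of positions 9 and 11. Sequences counted under a retrotransposon name although they map widely do not account for it either, since young L1 sequences that mapped to 1 position exceeded mRNA sequences by 14.98 points. Reciprocal cleavage, a biological explanation that requires 5' ends 10 nt apart, stays a hypothesis. Its prediction was met, with a partner at 10 nt for 55.3% of young L1 5' ends, against at most 43.8% at 11 to 20 nt. That comparison cannot decide, because A at position 10 pairs with a first T and so raises the value at 10 nt by itself. Random mRNA partners gave 12.2% against at most 8.43%. The ratio to the mean of the other overlaps was 1.475 with them and 1.35 within the list. With A required at the pairing position, the ratio was 1.23 within young L1, 1.14 with mRNA partners and 1.17 with IAP partners. Among such sequences that map to 1 position, the ratios were 1.94, 1.13 and 1.45. Composition was thus not fully separated, and which libraries carried the pairs stays open.

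Sequences with T first lined the sense strand of long noncoding and messenger RNAs, and phased production, in which a 3' end is followed directly by the next 5' end, was tested as a candidate explanation. A 5' end followed at 1 nt for 28.97% of 3' ends on noncoding genes, below the highest share of 29.5% at 2 to 20 nt, and for 6.41% on coding genes, below 6.73%. The base after the 3' end was T in 25.7% and 25.1%, as at the positions after it. This argues against phasing that is visible in the 3' ends as sequenced. Trimming of 3' ends, which would hide it, and the relative abundance of the sequences were not tested.

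A few miRNA hairpins had many sequences of piRNA length, since the 7 with at least 50 such sequences, led by mir-469 (398), mir-689 (348), mir-464 (291) and mir-468 (284), held 44.1% of the hairpin sequences of 24 to 33 nt. Mir-546 and mir-692 were picked after their values were seen, which were the highest of the 7 for T first and transcript matches. T was first in 81.9% (73.2 to 88.7) of their sequences, above other structural RNA (47.2%) and the bound set for structural fragments. A longer host transcript may be the source, since all 105 (100%) matched a transcript other than a miRNA. The matches lay in Ctdsp2 for mir-546 and in Ftl1 or related genes for mir-692. For mir-689, T was first in 10.9% (7.84 to 14.7), below ribosomal (31.1%), transfer (31.6%) and other structural RNA (47.2%). This met the bound set for structural fragments but resembled none of these classes. The share of T in single hairpins cannot identify a source, so it decides neither case. For the 7 together, T was first in 40.7% (38.2 to 43.2), or 49.7% (46.7 to 52.6) without mir-689. This lay between or across the structural classes, so structural fragments stay open. On either strand, 8.54% (7.18 to 10.1) matched such a transcript, a range that includes the bound of 10% set beforehand. The 23 matches of mir-468 were antisense to Stambp, which a host transcript would not give. None of the sequences of mir-464, mir-469, mir-689 and mir-805 matched one. Sense matches thus came only from mir-546 and mir-692, which argues against annotated spliced transcripts as the source for the others of the 7. Introns were not searched, so a source in the intron of an annotated gene stays open.

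On transcripts too, 5' ends of opposite strands met at an overlap of 10 nt more often than at the other overlaps from 1 to 30 nt. The shares were 2.33% against a mean of 1.54% and a highest other value of 1.76% on noncoding genes, and 0.333% against 0.187% and 0.258% on coding genes.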
